A study of Mus musculus with 4 samples.

How the data were processed

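Gene expression was measured in mouse Ly6C-high monocytes, sorted from pooled bone marrow of 3 mice and cultured with GM-CSF and interleukin 4, each at 20 ng per ml, per the labels' protocols. These cytokines drive monocytes toward dendritic cells. Retinoic acid at 100 nM or the solvent DMSO was present from the start, and total RNA was taken after 24 h. Per the labels' protocols, biotin-labelled cDNA was made from 250 ng of RNA with the Affymetrix WT PLUS kit and read on 1-colour arrays. There were 4 arrays, 2 with retinoic acid and 2 with DMSO. The labels do not say whether replicates with the same treatment came from separate cultures or separate pools of mice. The p-values of single probe sets therefore measure only the spread between these samples, which may be technical.

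The authors deposited 1 intensity per probe set and array. Per the submitters' processing notes, the values came from Affymetrix Expression Console with RMA, a method that corrects background, equalises the distributions of probe intensities and summarises probes into probe sets. No tool version was given in the sources used here, nor a genome build, so no coordinates are printed. The deposited intensities are on a linear scale: array medians over tested probe sets lay between 80.0 and 81.8. They were transformed to log2 here and not normalized again. Because RMA smooths background, differences of dim genes are understated. The files give no detection calls. As a guide to dim levels, chosen after the data were seen, the 95th percentile of the mean log2 intensity over 1400 olfactory and vomeronasal receptor probe sets was taken, which was 6.35. The number of arrays limits the precision.

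The table held 41345 probe sets. Of these, 1624 carried the identical lowest intensity, 4.78, on all 4 arrays, and none of them had an annotated gene. Their constant value was seen before any test was run. The test set before the data were examined was worded to cover every probe set not annotated as a control, these included. With these zero-variance probe sets kept, limma's prior degrees of freedom were 0.898 in place of 2.76, and no probe set passed the threshold. They were left out here, which departs from the test as worded and left 39721 probe sets. This choice was made after both counts had been seen, and both are given with the results. The calls of single probe sets, the counts of list members that rose or fell and the choice of named genes rest on it. The tests of whole lists use only named genes and stand as set beforehand. Data were simulated from these arrays' means with independent errors (20 sets, 200 changed probe sets of 39721). The error variances followed limma's prior from the fit without the constant probe sets. Leaving the constant probe sets out recovered 42.3% of changes of 2-fold and 92.1% of changes of 4-fold, with 5.04% false calls among all calls. Keeping them recovered 0.5% and 14% of the same changes. Since the simulation follows the fit without them, it favours that fit and does not decide between the choices. Only 0.6% of changes of 1.5-fold were recovered with them left out.

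Gene names came from the platform annotation. It listed 25335 probe sets, 23521 with 1 symbol and 1814 with several, and left 16010 unnamed here. Of the 23521 gene identifiers, 23328 were found in the mouse RefSeq gene table of assembly GRCm38.p6, and no symbol changed. No gene was named from a probe set with several symbols. A gene with more than 1 probe set was represented by the one with the highest mean over the 4 arrays, which gave 22180 genes.

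Retinoic acid was compared with DMSO by limma (version 3.58.1, R 4.3.3), with lmFit and eBayes on log2 values of all 4 arrays, two-sided, without covariates. P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, and an adjusted p under 0.05 was the threshold. An exact permutation test of 2 arrays against 2 cannot give a p under 0.333, so every p rests on limma's model. Differences are given as the mean log2 value with retinoic acid minus that with DMSO, with limma's moderated standard error (SE). Group levels are means ± SD (n = 2).

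Gene lists were fixed before the data were examined. There were 22 lists, of biological groups, of stress genes and of markers of other bone marrow cells. List genes without a probe set of their own by name were not analysed here. Each list was compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 22 lists. With that preset, camera's p-values take genes as the units, as do those of the gene family and neighbouring gene tests below. They do not measure the spread between arrays. Camera with an estimated correlation and fry, which asks whether a list's own genes move on balance one way, were alternatives. With an estimated correlation, limma's camera rests on the 2 residual degrees of freedom of these arrays. Few lists could then pass over 22 tests, even where the estimated correlation is low. In simulated data, genes varied independently. At an unadjusted p under 0.05, camera there called 20 of 20 lists of 25 genes shifted by 0.5 (log2) and 2 of 20 unshifted lists. This does not test the preset for lists of correlated genes, such as cholesterol synthesis with an estimated correlation of 0.177.

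Named genes followed a rule fixed beforehand. They are the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold (leaving out predicted gene models, small RNAs, receptor families of smell and antigen receptor segments), up to 4 members of each list with the largest absolute change past the threshold, and 18 genes of retinoic acid signalling and myeloid identity whatever their result. Of those 18, 1 is not reported here. Members outside this rule are named only to complete a small count and were chosen after their values were seen.

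The alternatives were the replicate number as a block, leaving out each array, filters on dim or unnamed probe sets, repeated quantile normalization, median centring, a variance trend with and without robust estimation, array weights, other thresholds, limma's treat against a fold of 1.2, other list tests and the mean of a gene's probe sets. A crossed pairing and the fit with the constant probe sets were added after the data were seen. No batch was named in the labels.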

Results

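The series measured how all-trans retinoic acid changes gene expression in Ly6C-high bone marrow monocytes on day 1 of a culture that promotes dendritic cell differentiation. Ly6C-high monocytes are precursors that can become dendritic cells or macrophages. Whole-transcript arrays were run on 2 samples with 100 nM retinoic acid and 2 with DMSO. Median intensities were 81.3 and 81.2 on the DMSO arrays and 80.0 and 81.8 on the retinoic acid arrays. Over 39721 probe sets, log2 intensities correlated at 0.9931 to 0.9943 (Pearson's r across probe sets, which are not independent replicates) within a treatment and at 0.9841 to 0.9879 between treatments. The first principal component held 62.1% of the variance and separated the treatments. The second held 23.9% and cut across them. DMSO replicate 1 and retinoic acid replicate 2 lay at 16.22 and 18.71, and DMSO replicate 2 and retinoic acid replicate 1 at -11.2 and -23.73. The labels name no factor that splits the arrays in this way. The median absolute difference between replicates was 0.114 on the log2 scale with retinoic acid and 0.104 with DMSO.

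Retinoic acid changed 830 of 39721 probe sets at a limma adjusted p under 0.05. Of these, 359 were higher and 471 lower, and 178 and 231 of them differed by at least 2-fold. At the level of genes, 284 rose and 397 fell among 22180. These counts rest on leaving out 1624 unnamed probe sets that hold one constant value, a choice made after the counts with and without them had been seen. In the test as worded beforehand, which kept them, limma called 0 probe sets (smallest adjusted p = 0.0535), with 330 higher and 372 lower at an adjusted p under 0.1 and 6260 at an unadjusted p under 0.05. The filter to probe sets with 1 symbol, an alternative set beforehand that also leaves them out, called 757 higher and 879 lower. The tests of whole gene lists use named genes and do not depend on this choice, whereas each single gene written of as having risen or fallen does. Without any 1 array, between 25 and 55 probe sets passed: 41 without DMSO replicate 1, 39 without DMSO replicate 2, 25 without retinoic acid replicate 1 and 55 without retinoic acid replicate 2. Among the 79 genes named by the rule, 74 passed, none of those 74 changed sign when an array was left out, 12 passed whichever array was left out and 47 passed in none of these 4 fits.

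**Figure D1:**
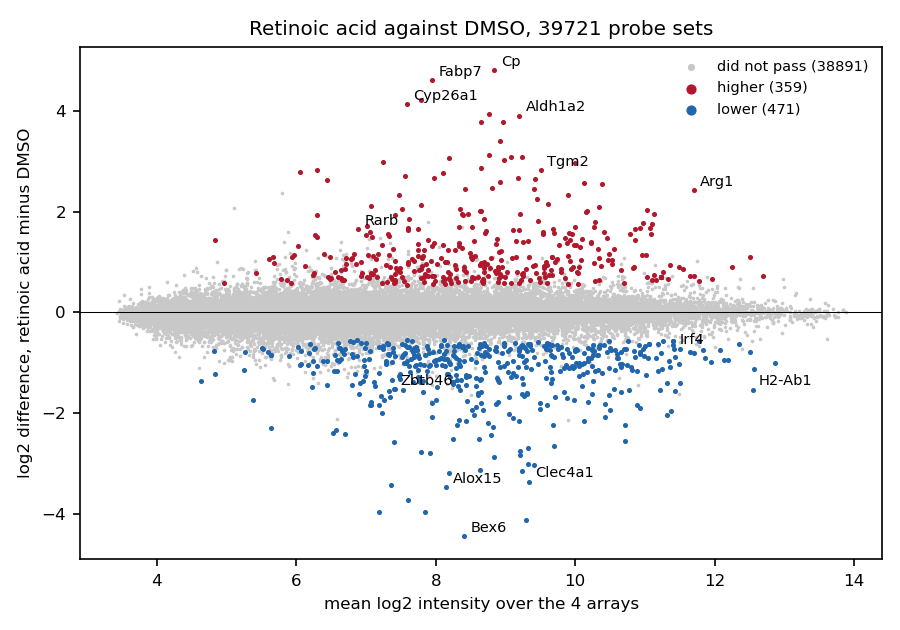
Log2 difference between retinoic acid and DMSO (vertical axis) against the mean log2 intensity over the 4 arrays (horizontal axis), 1 point per tested probe set. The 359 probe sets higher with retinoic acid are red, the 471 lower ones blue and the rest grey; Cp and Bex6 lie at the upper and lower ends of the labelled genes.

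Among genes open to naming, the largest rise was in Cp (ceruloplasmin, a copper-carrying ferroxidase; probe set 17396260), from 6.44 ± 0.16 to 11.25 ± 0.18 (log2 intensity, SD, n = 2), a 28.0-fold increase. Fabp7, a fatty acid binding protein, rose 24.5-fold, Cyp26a1, the cytochrome P450 that degrades retinoic acid, 17.6-fold, and Aldh1a2, an enzyme that makes retinoic acid, 15-fold. Fabp7 and Cyp26a1 lay under the dim level of 6.35 with DMSO, so their folds and ranks are against background. Cp with DMSO lay close to that level, with DMSO replicate 2 at 6.33, so its fold and rank are close to background as well. Adgre4, an adhesion receptor of the F4/80 family, rose 13.7-fold, with the 2 retinoic acid arrays apart by an SD of 0.66. Acp5, the tartrate-resistant acid phosphatase, rose 10.5-fold, the chemokine Cxcl14 8.72-fold, Smpdl3a 8.51-fold and the cytokine Il1a 8.45-fold; a second, dimmer probe set of Smpdl3a rose 2.24-fold (adjusted p = 0.0358). Rbpms, an RNA-binding protein, rose 8.15-fold, Asb2, a ubiquitin ligase subunit, 7.29-fold, and Tgm2, transglutaminase 2, 7.08-fold. The adjusted p of these 12 genes (limma) ran from 0.00174 to 0.0192. Cp, Fabp7, Aldh1a2, Acp5, Cxcl14 and Rbpms passed without any 1 of the arrays.

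The largest fall was in Bex6 (probe set 17324745), from 10.63 ± 0.14 to 6.18 ± 0.25 (log2 intensity, SD, n = 2), which was 21.7-fold lower. The C-type lectin Cd209c was 15.6-fold lower and the lipid-oxidising enzyme Alox15 11.1-fold lower. The neighbouring receptor genes P2ry10 and P2ry10b were 13.2-fold and 9.21-fold lower. The membrane protein gene Ms4a4a was 10.8-fold lower, and the lectin gene Clec4a1 10.3-fold lower. Scimp, an adaptor that associates with MHC class II, was 8.85-fold lower, the water and glycerol channel Aqp3 8.74-fold, the neurturin receptor Gfra2 8.16-fold, the protease-activated receptor F2rl2 8.05-fold and Sema6d, a semaphorin, 7.37-fold. The adjusted p of these 12 genes (limma) ran from 0.00174 to 0.0141. P2ry10 and P2ry10b, and Cd209c and its relatives, are similar genes whose probes may share targets, and a dimmer probe set of Cd209c differed by -0.11 ± 0.09 (log2, SE; adjusted p = 0.67). Bex6, Cd209c, P2ry10 and Ms4a4a lay under the dim level with retinoic acid, so their folds and ranks are against background. Alox15 with retinoic acid lay close to that level, at 6.41, with retinoic acid replicate 1 at 6.33. A probe set of Cd209a that does not represent its gene here was 17.4-fold lower (limma adjusted p = 0.00174). It stands outside this ranking, since a gene is represented by its probe set with the highest mean over the 4 arrays. Bex6, Cd209c, P2ry10, Ms4a4a, Scimp and Aqp3 passed without any 1 of the arrays.

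**Figure D2:**
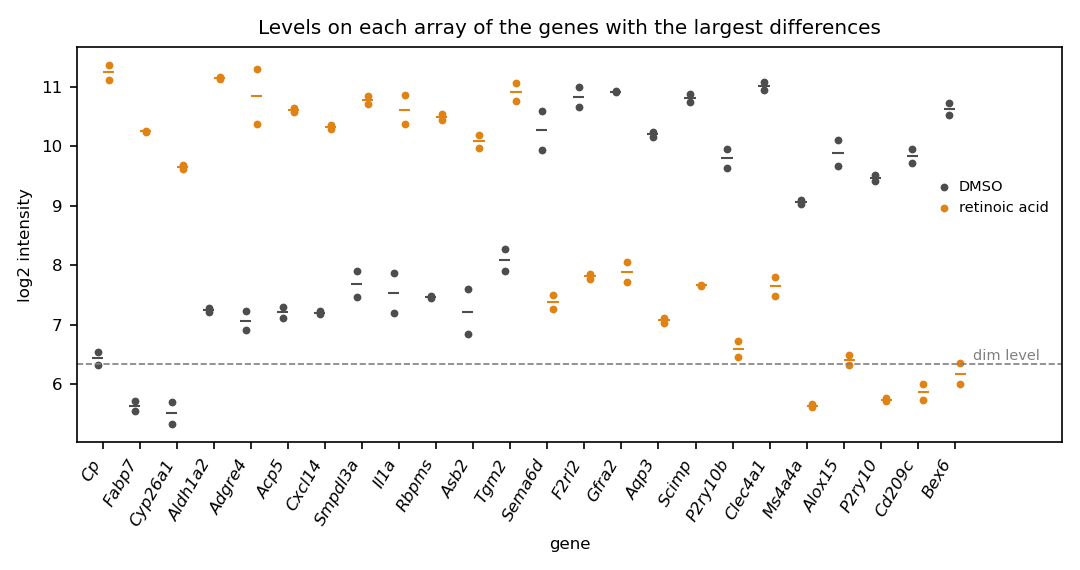
Log2 intensity (vertical axis) on each array for the 12 genes with the largest rise and the 12 with the largest fall (horizontal axis), with DMSO in dark grey and retinoic acid in orange. Points are single arrays, short lines group means (n = 2), and the dashed line is the dim level of 6.35. The arrays of the 2 treatments do not overlap for any of these genes, which were chosen for large differences past the threshold.

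Of 22 measured retinoic acid response genes, 11 rose, 2 fell and 9 did not pass (12 rose and 2 fell when adjusted over the list alone), with a median log2 difference of 0.63 (1.53 among probe sets brighter than the median). Besides Cyp26a1, Aldh1a2, Asb2 and Tgm2, the retinoid reductase gene Dhrs3 rose 6.30-fold (log2 difference 2.66 ± 0.17, SE, adjusted p = 0.00834). Rarb, the retinoic acid receptor whose own gene is a classical target, rose 3.13-fold from a level under the dim level (adjusted p = 0.00652), and Cyp26b1, another retinoic acid hydroxylase, 1.99-fold (adjusted p = 0.0170). The members that fell were receptor genes: Rara was 2.28-fold lower (log2 difference -1.19 ± 0.09, adjusted p = 0.0116), and Rarg, named to complete the count, changed by -0.85 ± 0.11 (adjusted p = 0.0403). Rxra, the shared partner of these receptors, was 2.71-fold lower (adjusted p = 0.0244). The retinol importer Stra6 differed by 0.03 ± 0.18 and the gut-homing receptor Ccr9 by 0.20 ± 0.13, and neither passed; Ccr9 in both groups and Stra6 with DMSO lay under the dim level, so these values do not show whether the genes responded. Camera placed the list above other genes (adjusted p = 6.65e-09; 0.253 with an estimated correlation). The estimated correlation, 0.00503, was under the preset 0.01. Of the other called lists, it was also under the preset for dendritic cell differentiation and macrophage identity. It was above it for MHC class II (0.0856), inflammatory (0.0969), interferon (0.108), cholesterol synthesis (0.177) and stress genes (0.0137). The preset may therefore make the p-values of those lists too small. Camera with an estimated correlation rests on 2 residual degrees of freedom and called 0 of the 22 lists. It therefore cannot tell whether correlation between genes undoes a list's call.

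In the wider list of retinoid uptake and metabolism, 4 of 27 measured genes rose, 1 fell and 22 did not pass (6 and 2 adjusted over the list alone). The 4 were Cyp26a1, Aldh1a2, Dhrs3 and Cyp26b1, which the response list also holds. Dhrs9, a dehydrogenase able to oxidise retinol, was 2.14-fold lower (adjusted p = 0.0198). Camera did not call this list (adjusted p = 0.0703; 0.42 with an estimated correlation). It was called without DMSO replicate 1 (adjusted p = 0.0334), among probe sets brighter than the median (0.0284) and by fry (0.0128), and the range over all alternatives was 0.0128 to 0.469.

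Of 28 measured genes of dendritic cell differentiation, 10 fell, 2 rose and 16 did not pass (19 fell and 3 rose adjusted over the list alone), with a median log2 difference of -0.70. The transcription factor genes Klf4 (3.83-fold lower), Id2 (2.97-fold) and Zbtb46 (2.88-fold), the last restricted among immune cells mainly to conventional dendritic cells, fell, as did the signalling adaptor Traf1 (3.50-fold), with adjusted p of 0.00834, 0.00492, 0.00492 and 0.00435. Irf4, a transcription factor needed for monocyte-derived dendritic cells, fell from 11.77 ± 0.05 to 11.05 ± 0.01 (log2 intensity, SD, n = 2), 1.65-fold lower (adjusted p = 0.0271). With the replicate number as a block, Irf4 did not pass (limma adjusted p = 0.124), while Klf4, Id2, Zbtb46 and Traf1 did (0.0377 to 0.0431). The integrin gene Itgax, which encodes CD11c, differed by -0.42 ± 0.08 and did not pass (adjusted p = 0.0949). Irf8, a factor of monocyte and dendritic cell fate outside this list, rose 2.12-fold in its brighter probe set (adjusted p = 0.0202), while the dimmer one, under the dim level, differed by 0.13 ± 0.10 (adjusted p = 0.658). The 2 members that rose, named to complete the count, were the activation marker Cd83 (0.99 ± 0.08, adjusted p = 0.0127) and the peptidase Dpp4 (1.12 ± 0.15, adjusted p = 0.0428). The 2 probe sets of Cd209a, which encodes the monocyte-derived dendritic cell lectin DC-SIGN, disagreed: the one with the higher mean over all arrays differed by 0.05 ± 0.09 (adjusted p = 0.875), and the other, at 11.36 ± 0.12 with DMSO, was 17.4-fold lower (log2 difference -4.12 ± 0.09, adjusted p = 0.00174). Camera placed the list below other genes (adjusted p = 1.26e-12; 0.253 with an estimated correlation). The list of stress and immediate early genes, fixed as a sign of handling and RNA quality, lay below other genes too (camera adjusted p = 6.02e-05; 0.285 with an estimated correlation), with a median log2 difference of -0.12.

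Of 15 measured genes of the MHC class II pathway, which presents antigen to CD4 T cells, 6 fell, 0 rose and 9 did not pass (8 fell adjusted over the list alone). H2-Eb1 was 4.23-fold lower, H2-Ab1 2.90-fold and H2-Aa 2.66-fold, with H2-Ab1 going from 13.31 ± 0.04 to 11.78 ± 0.01 (log2 intensity, SD, n = 2). Ciita, the master activator of these genes, was 3.51-fold lower (adjusted p = 0.00733). With the replicate number as a block, H2-Eb1, H2-Ab1 and H2-Aa passed (limma adjusted p = 0.0377, 0.0431 and 0.0471) and Ciita did not (0.0519). The estimated inter-gene correlation of the list was 0.0856, above the preset 0.01. Over the list the median log2 difference was -0.41, and camera placed it below other genes (adjusted p = 6.81e-09; 0.285 with an estimated correlation), as it did the stress and immediate early genes (adjusted p = 6.02e-05; 0.285 with an estimated correlation).

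Of 29 measured macrophage identity genes, 4 rose, 1 fell and 24 did not pass (7 and 2 adjusted over the list alone), with a median log2 difference of 0.21 (0.13 without DMSO replicate 1, and 0.31 among probe sets brighter than the median). The complement gene C1qb rose 2.20-fold, the lipid receptor Trem2 2.01-fold and the scavenger receptor Stab1 1.82-fold, with adjusted p of 0.0212, 0.0186 and 0.0213; C1qc, named to complete the count, changed by 0.82 ± 0.09 (adjusted p = 0.0294). Vcam1, an adhesion molecule, was 1.85-fold lower (adjusted p = 0.0329). With the replicate number as a block, C1qb, Trem2, Stab1 and Vcam1 did not pass (limma adjusted p = 0.101, 0.0813, 0.09 and 0.131). Csf1r, the receptor for the macrophage growth factor CSF-1, differed by -0.005 ± 0.075 (adjusted p = 0.989). Camera placed the list above other genes (adjusted p = 0.0117; 0.411 with an estimated correlation), and fry, which tests the list on its own, did not call it (adjusted p = 0.0673).

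Monocyte genes moved in both directions. Of 18 classical monocyte genes, 4 rose, 5 fell and 9 did not pass (7 and 7 adjusted over the list alone). Clec4a1, the coagulation factor gene F13a1 (3.99-fold lower, adjusted p = 0.00435), the calcium-binding S100a4 (3.46-fold lower, adjusted p = 0.00502) and Ms4a4c (3.09-fold lower, adjusted p = 0.0134) fell, and S100a6 completes the count (-1.58 ± 0.14, adjusted p = 0.0155). F13a1 and Ms4a4c lay under the dim level with retinoic acid, so their folds are against background. The 4 that rose, named to complete the count, were the matrix gene Fn1 (1.10 ± 0.14), Mgst1 (1.04 ± 0.14), haptoglobin Hp (0.97 ± 0.09) and the glutathione reductase Gsr (0.90 ± 0.08), with adjusted p from 0.0148 to 0.0426. Of 15 non-classical monocyte genes, Adgre4, Apoc2 (1.76-fold, adjusted p = 0.0213) and Pou2f2 (1.6-fold, adjusted p = 0.0333; under the dim level with DMSO) rose, the integrin gene Itgal was 3.79-fold lower (adjusted p = 0.00654) and 11 did not pass (5 rose and 3 fell adjusted over the list alone). Camera called neither list (adjusted p = 0.378 for each; 0.635 and 0.55 with an estimated correlation).

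Of 26 interleukin 4 response genes, Arg1 rose, Alox15 and Cdh1 fell and 23 did not pass (6 and 9 adjusted over the list alone). Arg1, the arginine-degrading enzyme, rose from 10.49 ± 0.45 to 12.92 ± 0.00 (log2 intensity, SD, n = 2), a 5.39-fold increase (adjusted p = 0.0173). Cdh1, which encodes E-cadherin, was 5.91-fold lower (adjusted p = 0.00312), and its second, dimmer probe set passed as lower too (adjusted p = 0.00466), with its level under the dim level with retinoic acid. Of 23 immune suppressive molecules, Arg1 and Trem2 rose, and the inhibitory receptor Havcr2 (4.08-fold lower, adjusted p = 0.00492) and the ectonucleotidase Entpd1 (2.22-fold lower, adjusted p = 0.0101) fell (6 and 4 adjusted over the list alone). Camera gave adjusted p of 0.249 and 0.742 for the lists (0.55 and 0.793 with an estimated correlation).

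Of 26 measured inflammatory cytokine and chemokine genes, 4 fell, 1 rose and 21 did not pass (8 and 2 adjusted over the list alone). The monocyte-attracting chemokines Ccl12 (5.07-fold lower, adjusted p = 0.0308) and Ccl7 (4.30-fold lower, adjusted p = 0.0144), Cxcl16 (2.39-fold lower, adjusted p = 0.0409) and, to complete the count, Osm (-0.97 ± 0.10, adjusted p = 0.0237) fell, while Il1a rose. Ccl12 with retinoic acid lay under the dim level, so its fold is against background. The list had a median log2 difference of -0.11 (-0.28 among probe sets brighter than the median). Camera placed the list below other genes (adjusted p = 0.0132; 0.55 with an estimated correlation), a call lost without retinoic acid replicate 2 (adjusted p = 0.336), with rank-based camera (0.168) and with fry (0.159), with a range over all alternatives of 0.00102 to 0.55. The stress and immediate early genes moved in that direction as well (camera adjusted p = 6.02e-05; 0.285 with an estimated correlation). Of 23 type I interferon response genes, the antiviral Oasl2 (2.14-fold, adjusted p = 0.0495) and the nucleic acid sensor Zbp1 (1.61-fold, adjusted p = 0.0349) rose, and Usp18, a brake on interferon signalling, was 2.31-fold lower (adjusted p = 0.0221; 6 rose and 3 fell adjusted over the list alone). Oasl2 with DMSO lay under the dim level. The interferon list had a median log2 difference of 0.19 (0.12 without retinoic acid replicate 2) and lay above other genes in camera (adjusted p = 0.0346; 0.55 with an estimated correlation), a call lost without DMSO replicate 2 (adjusted p = 0.0593) or retinoic acid replicate 1 (adjusted p = 0.157), among probe sets brighter than the median (0.0597) and with fry (0.159), with a range over all alternatives of 0.00768 to 0.55.

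Of 17 measured cholesterol synthesis genes, 2 fell, 1 rose and 14 did not pass (11 fell and 2 rose adjusted over the list alone), with a median log2 difference of -0.39. Lss and Sqle, consecutive steps of sterol ring formation, were 2.04-fold (adjusted p = 0.0328) and 1.59-fold lower (adjusted p = 0.0480), and Sc5d, a late step, rose 1.9-fold (adjusted p = 0.0232). Camera placed the list below other genes (adjusted p = 3.99e-06; 0.411 with an estimated correlation), and fry did not call it (adjusted p = 0.0623). Among 19 targets of the lipid receptors LXR and PPAR, the lipid exporter Abca1 rose 2.50-fold (adjusted p = 0.0157) and its relative Abcg1 was 1.68-fold lower (adjusted p = 0.0280; 3 rose and 2 fell adjusted over the list alone), and camera did not call the list (adjusted p = 0.742; 0.854 with an estimated correlation), whose median of -0.05 and mean of 0.03 differ in sign. None of 28 cell cycle genes passed in limma, 0 also when adjusted over the list alone, 8 had an unadjusted p under 0.05, and their median log2 difference was 0.02 (camera adjusted p = 0.593; 0.635 with an estimated correlation). Of 21 stress and immediate early genes, the phosphatase Dusp1 (2.50-fold lower, adjusted p = 0.00751), Ier3 (1.84-fold, adjusted p = 0.0314) and Junb (1.6-fold, adjusted p = 0.0399) fell, 0 rose (5 fell adjusted over the list alone), and camera placed the list below other genes with an adjusted p of 6.02e-05 (0.285 with an estimated correlation).

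Camera called none of the 7 lists of markers of other bone marrow cells. Of 20 genes of granulocyte maturation and neutrophils, Mmp9 rose 2.01-fold (adjusted p = 0.0497). Retnlg also passed as higher (adjusted p = 0.0228), at 5.08 with DMSO and 6.14 with retinoic acid, both under the dim level, so no fold is given, and the chemokine receptor Cxcr2 was 2.22-fold lower (adjusted p = 0.0168; 3 rose and 1 fell adjusted over the list alone). The neutrophil list's median log2 difference was -0.02 and its mean 0.09, which differ in sign, and 1 of its genes stands in another list too. Of 13 B cell genes, Bank1 and Cd79b rose 1.59-fold (adjusted p = 0.0427), from a level under the dim level, and 1.57-fold (adjusted p = 0.0473; 2 rose and 1 fell adjusted over the list alone). Of 7 eosinophil genes, Siglecf rose 1.52-fold (adjusted p = 0.0489; 1 rose adjusted over the list alone). None of 17 T cell and NK cell, 12 plasmacytoid dendritic cell, 13 basophil and mast cell or 11 erythroid and megakaryocyte genes passed in limma, while 1, 4, 1 and 1 of them had an unadjusted p under 0.05. Adjusted over the list alone, 2 plasmacytoid genes rose and 1 fell, and 0 genes of the others did. The erythroid and megakaryocyte list had a median of 0.01 and a mean of -0.01. With DMSO, 18 of 20 neutrophil, 3 of 13 B cell, 3 of 7 eosinophil, 6 of 17 T cell and NK cell, 8 of 12 plasmacytoid, 6 of 13 basophil and mast cell and 7 of 11 erythroid and megakaryocyte genes lay above the dim level, and 2 plasmacytoid genes stand in another list too. Camera's adjusted p for the cell type lists ran from 0.332 to 0.867 (0.55 to 0.877 with an estimated correlation).

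**Figure D3:**
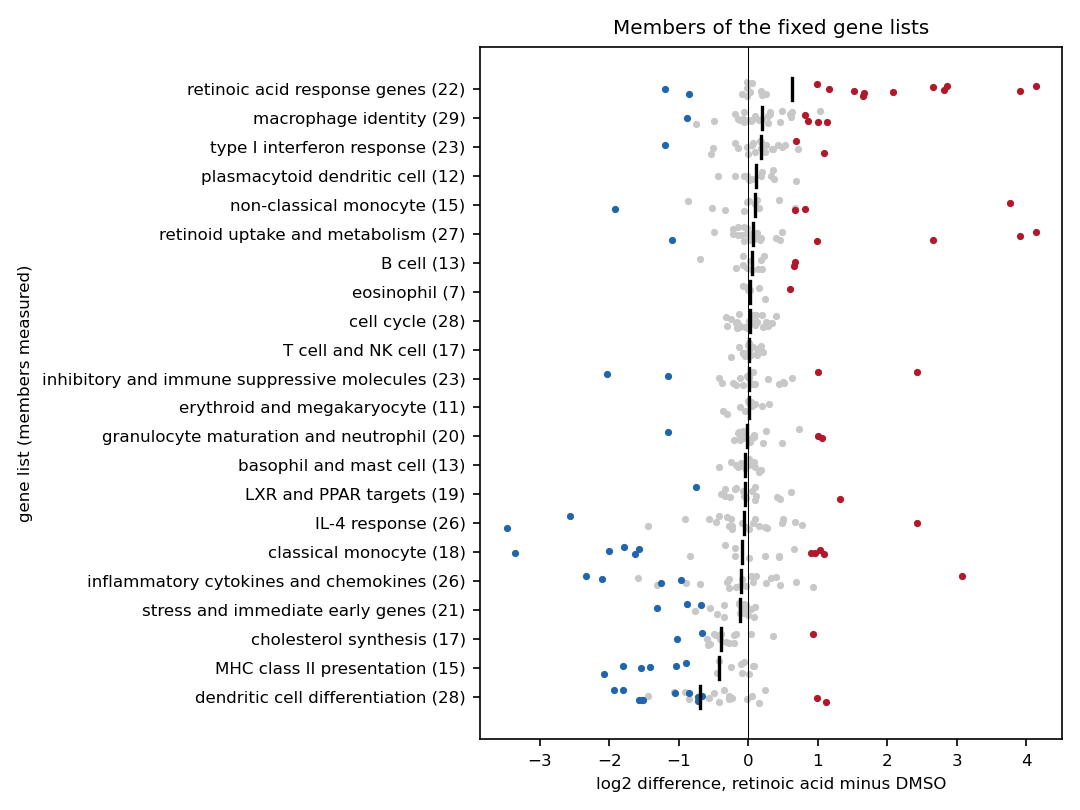
Log2 difference between retinoic acid and DMSO (horizontal axis) for each measured member of the 22 lists (vertical axis, number of members measured in brackets), with members that rose in red, fell in blue and did not pass in grey, and black bars at list medians. The medians run from -0.70 for dendritic cell differentiation to 0.63 for retinoic acid response genes.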

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

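The crossed pairing was added, and leaving out the 1624 constant probe sets was chosen, after the data were seen. In the test as worded beforehand, with them kept, 0 probe sets were higher and 0 lower at an adjusted p under 0.05, and 330 and 372 passed 0.1; their zero variances lowered the prior degrees of freedom from 2.76 to 0.898. Testing only probe sets with 1 symbol, which leaves all of them out, called 757 higher and 879 lower, and the 1636 included all 696 single-symbol calls. Leaving out 1 array called 12 to 30 higher and 13 to 25 lower, with 3533 to 5316 probe sets at an unadjusted p under 0.05, and 1 residual degree of freedom; the lone array was assumed to vary like the other group. With the replicate number as a block, 73 were higher and 88 lower (159 of these 161 shared with the unblocked calls), and 38 of the 74 named genes that passed still did. The labels do not say that equal replicate numbers share a culture or a pool of mice, so the numbers were not taken as pairs. The deviations of same-numbered arrays from their group means correlated at -0.251 across probe sets. The crossed pairing called 191 higher and 260 lower. An adjusted p under 0.1 gave 637 and 773, a further 2-fold requirement 178 and 231, and treat against a fold of 1.2 gave 181 and 232. The dim filter (535 and 658), quantile normalization, median centring, the variance trend with or without robust estimation and array weights kept both counts within 1.5 times. Of the 22 lists, 8 were called by camera, 0 with an estimated correlation, 20 by the mixed form of fry, which asks whether members change in either direction, and 5 by fry, where the retinoid metabolism list was added and the macrophage, inflammatory, interferon and cholesterol lists were lost. Blocking left the 8 list calls unchanged. Repeated quantile normalization, median centring and array weights turned the sign of no named gene that passed. The block, the dim filter, the single-symbol filter and the variance trend leave a gene's own difference unchanged by construction, so they do not test its sign. The mean of both Cd209a probe sets was -2.03 (adjusted p = 8.19e-05; over the alternatives 8.19e-05 to 0.983), against 0.05 for the one that represents the gene. Itgax, which did not pass, passed with 1 symbol per probe set, with either variance trend and with means of probe sets (adjusted p = 0.0230, 0.0172, 0.0195 and 0.0208; over the alternatives 0.0172 to 0.381). The robust setting was not run for the lists, and the single-symbol filter does not alter them by construction. Depth in the sense of reads does not apply, and genes under the dim level carry little information on direction.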

Other observations

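The tests of gene families, of B cells and of the dendritic cell and macrophage lists in this part, and the treatment of neighbours with one name stem as a pattern of their own, were chosen after the results were seen; the permutation tests of neighbouring genes and their bounds were set before, but the pattern that the paralog test bears on was narrowed to different name stems afterwards.

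Several gene families held more changed genes than their size gives; some members, such as Ms4a4c and S100a4, also stand in the fixed lists, and the families and Ighm were singled out after their values were seen. Families were taken as genes whose symbols differ only in their last number and letters or after a hyphen, with at least 5 measured genes, and 1338 combinations of family and direction were tested by Fisher's exact test, one-sided. Of 20 measured Ms4a genes, which encode membrane proteins with several passes, 5 fell: Ms4a4a, Ms4a4c, Ms4a6c, Ms4a6d and Ms4a3 (adjusted p = 0.0149). Of 9 P2ry genes, which encode receptors for nucleotides and lipids, P2ry1, P2ry6, P2ry10 and P2ry10b fell (adjusted p = 0.0149). Of 15 S100a genes, S100a4, S100a6, S100a10 and S100a11 fell (adjusted p = 0.0395). Of 8 Gimap genes, GTPases of immune cells, Gimap5, Gimap6 and Gimap9 rose (adjusted p = 0.0395), and of 10 interferon-inducible Gbp genes, Gbp8, Gbp9 and Gbp10 rose, without the family passing its test (adjusted p = 0.0624). With repeated quantile normalization or median centring, each of these members kept its direction; 1 of the 5 Ms4a genes no longer passed with centring, and 1 of the 3 Gbp genes with quantile normalization. Members of a family are not independent, and their probes can share targets.

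Genes that changed lay next to genes that changed the same way more often than chance gives. Among 18954 protein-coding genes in the order of the GRCm38.p6 gene table, 659 changed, and 49 neighbouring pairs changed in one direction. Permuting the calls 10000 times within 20 bins of mean level gave 14 pairs on average and 32 at most (permutation p = 1e-04, the smallest that these permutations can give), which argues against bright genes lying together as the cause. Leaving out neighbours whose symbols start with the same letters, 34 pairs remained, such as Fabp7 with Smpdl3a or Aqp9 with Aldh1a2, against a permuted mean of 13.5 and maximum of 30, which argues against binding of paralog RNA as the whole cause, although some paralogs have unlike names (Treml2 and Trem2 each lie beside B430306N03Rik); for the other 15 pairs, among them Clec4n with Clec4d and Tmem176a with Tmem176b, it cannot be told apart, since probe sequences were not used. A candidate explanation for the 34 pairs is regulation over chromosome neighbourhoods, which was not tested, and transcripts that run into the next gene stay open too.

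Ighm, which encodes the IgM heavy chain, rose 3.18-fold in its brightest probe set, from 10.24 to 11.91 on the log2 scale (adjusted p = 0.00652); of its 7 probe sets, the next brightest differed by 0.86 (adjusted p = 0.0653). This stood beside the rises of Cd79b and Bank1. More B cells in the retinoic acid cultures cannot be told apart from other sources. Of the 13 B cell markers, 5 lay above the dim level with retinoic acid and 3 with DMSO. Those 5 had a median log2 difference of 0.19 against 0.06 over all 13, which is too few to decide. Choosing them by their level with retinoic acid favours markers that rose, such as Bank1, so 0.19 may be too high. Over all 13, the median was 0.17 without retinoic acid replicate 1 and 0.02 without DMSO replicate 2. Levels of different probe sets are not on one scale. The sort for Ly6C-high monocytes would remove most B cells; plasma cells, which the list does not cover, and transcription of the locus in myeloid cells may be explanations too and were not tested.

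The lower dendritic cell and MHC class II genes could come from RNA of cells of another lineage diluting the monocyte-derived cells, or from a shift toward macrophage genes. Dilution by cells that lack both groups of genes would lower macrophage genes alike, yet the macrophage list's median lay 0.90 above that of the dendritic cell list on the log2 scale, and 0.75 to 0.87 above it in the 4 pairs of a retinoic acid and a DMSO array, which argues against such dilution as the whole cause. The 4 pairs share arrays, so they are not separate replicates, and both list medians were known before this comparison was chosen. The lists' members are not independent, and a diluting cell type that expresses the macrophage genes stays open. A shift toward macrophage genes stays open. That list was higher in camera with the preset correlation (adjusted p = 0.0117), while fry did not call it (adjusted p = 0.0673). Camera with an estimated correlation gave an adjusted p of 0.411. That form called 0 of the 22 lists, so it cannot decide this. Bulk RNA of a whole culture cannot separate a change within cells from a change in the share of cells.

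The probe set of Cd209a with the higher mean over the 4 arrays differed by 0.05 between treatments, and the other, which was the brighter one with DMSO (11.36 against 9.89), by -4.12. Of 50 genes with several probe sets and any call, 8 had every probe set called and 0 were called in both directions. Among 14386 probe sets without a name here, 47 were higher and 50 lower with retinoic acid.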
